A study of Mus musculus with 15 samples.

How the data were processed

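Substantia nigra RNA of 15 libraries from 8 mice was sequenced after polyA selection, with strand kept, per the labels' protocols. The 3 injected and 3 uninjected libraries of miR-181 mice were read as 75-base pairs on a HiSeq. The 4 injected and 5 uninjected libraries of GFP mice were read as 50-base pairs on a NovaSeq. Reads were assigned to GRCm38 transcripts with kallisto 0.43.1 and modelled with sleuth 0.30.0, per the submitters' processing notes, which do not state the number of bootstraps or how transcripts were combined into genes. The deposited values of each library were read as a signal, TPM divided by 1 size factor per library. This reading was inferred from the sums, which ran from 970505 to 1040288 without repeated rows, where TPM of all genes would have a fixed sum. The authors normalized the miR-181 and GFP tables separately. The file headers name neither the tests nor the log of the authors' statistics. The 2 deposited p-values equal those of a Wald test and of a likelihood ratio test, recomputed from the deposited coefficients, errors and statistics, to within 0.00483 of their size. The deposited coefficients of called genes had a median ratio to the log2 change of 0.717 and 0.729 in the 2 tables, near the 0.693 of a natural log, and were read as natural logs. Recomputing these was added after the data were seen. The deposited residual sums equal the variance times the number of libraries less 1 for each gene, as in a model with an intercept only. The likelihood ratio test against that model had 1 degree of freedom. The fuller model thus added 1 coefficient, that of injection, and was read as having no term for mouse.

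Each table had 56305 rows, of which 36660 held values; 395 rows that repeated a gene identifier were left out, which left 36265 genes, and 35859 of these identifiers were in the GENCODE M21 annotation of GRCm38. Leaving out repeated rows was decided after the data were seen. Genes were tested by identifier, and 77 symbols were shared by more than 1 identifier. The depth of single libraries cannot be recovered from TPM, so values carry no counting intervals; the deposited mean estimated counts, summed over genes, came, in units of 1e+06, to 22.1 for the miR-181 table and 9.68 for the GFP table. The 10 most abundant genes took between 9.52% and 15.7% of a library. Replicates of a group correlated at between 0.961 and 0.986 (Pearson, across genes), and 0 columns were identical. The planned test assumed TPM. The values were read as TPM divided by a size factor, for which the same test was used.

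Values were compared as log2(value + 0.5) with limma 3.58.1 in R 4.3.3, with an intensity trend and Benjamini-Hochberg adjustment at 0.05, for genes with a mean of at least 1 over the libraries of the comparison. A fold on this scale understates the change of low genes. The 3 comparisons were injected against uninjected sides of miR-181 mice, the same in GFP mice, and the per-mouse log2 change of 3 miR-181 mice against that of 4 GFP mice. The 38 gene lists, with 522 symbols of which Park2 had no values, were tested in the 3 comparisons (114 tests, adjusted together) with camera at a preset correlation of 0.01; an estimated correlation and fry were alternatives. No camera call held with an estimated correlation. For the difference, camera ran without the intensity trend, a choice made after the data were seen. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined.

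Seed matches of miR-181 (7 bases of the TGAATGT or GAATGTA kind; 8 bases as TGAATGTA) were counted in the longest annotated 3' UTR and, separately, in the coding sequence of each gene with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The rank-sum score of TGAATGT was ranked among all heptamers counted in the same sequences. Ranks in single mice were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

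Genes were named by rule: the 10 largest rises and falls among called genes with the same sign in each mouse (predicted models only where no other gene was left) and the 4 members of each list with the smallest p. Always named were Th, Slc6a3, Slc18a2, Gfap, Aif1 and the miR-181 host transcript. For the difference the mice of both sets had not to overlap. Some genes the rule names are not reported here. From the list members so named, those described in the text were selected after their values were seen. Gm21830, called for the difference, is named outside the rule as one of 5 calls, as is the pituitary set, both after their values were seen.

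Both sides of a mouse come from the same animal per the labels, so the mouse numbers pair the libraries. Deviations from the group mean correlated between the sides of a mouse at 0.183, 0.140 and 0.257 in miR-181 mice and 0.192, 0.0947, 0.0177 and 0.122 in GFP mice. Alternatives were other pseudocounts and filters, quantile normalization, median centring, no intensity trend, mouse as a block, each library or mouse left out in turn, and the q-values of the authors. Added after the data were seen were rescaling each library to the same sum, leaving out both libraries of miR-181 mouse 2 or of GFP mouse 1, and keeping repeated rows.

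The steps were tested on simulated data with 50 genes changed at each fold size. Of genes changed by 0.32 log2 units, the smallest size, 16%, 16% and 12% were recovered in the miR-181 comparison, the GFP comparison and the difference. Of genes changed 1.5-fold, 2-fold and 4-fold, 54%, 72% and 96% were recovered in the miR-181 comparison, with 7 false calls. In the GFP comparison it was 64%, 78% and 94%, with 2 false calls, and for the difference 44%, 74% and 94%, with 4. Of 100 unchanged lists, 0, 2 and 6 had a camera p under 0.05 in the 3 comparisons. Genes were simulated independently, so these counts do not cover lists whose members vary together. In the miR-181 comparison the estimated correlation of the interferon list was 0.907. A simulated seed shift of -0.05 log2 units ranked TGAATGT first in 5 of 5 draws of the miR-181 comparison, and without a shift its rank lay between 125 and 14525. For these draws the log2 changes were shuffled across genes, which removed their relation to 3' UTR length and composition. The simulated ranks therefore do not carry over to the measured changes.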

Results

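RNA sequencing measured transcript abundance in the substantia nigra, the midbrain region whose dopamine neurons are lost in Parkinson disease, of 8 C57Bl/6J mice 3 weeks after a virus injection on 1 side. In 3 mice the adeno-associated virus (AAV) carried miR-181, a microRNA, under the human synapsin promoter, which acts in neurons. The other 5 mice belonged to the GFP set, given an AAV with the same promoter and a green fluorescent protein, and the other side of each animal stayed uninjected. There were 3 injected and 3 uninjected libraries of miR-181 mice, and 4 injected and 5 uninjected libraries of GFP mice; GFP mouse 5 gave an uninjected library only. All values below were read as TPM divided by a size factor per library. Such values keep no record of depth, so the depth of each library is unknown; between 15022 and 15563 genes reached a value of 1 in a library. The 2 sets of mice were prepared, sequenced and normalized separately, at 1.65e10 vector genomes for miR-181 and 1e10 for GFP, so vector, dose, sequencer and library set change together. The dissected tissue may differ too, since serotonin neuron genes stood far higher in the miR-181 libraries.

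The first comparison asked which transcripts differed on the side given miR-181. Cd74, the invariant chain of MHC class II, rose from 22.5 ± 10.1 to 622 ± 205 (SD, n = 3 per side), a log2 change of 4.79 ± 0.33 (SE; limma adjusted p = 0.00225). Ccl5, a chemokine that attracts T cells, rose from 1.84 ± 0.692 to 128 ± 91.8 (log2 5.56 ± 0.51; limma adjusted p = 0.00374). C4b, a complement component made by glia, rose from 46.3 ± 1.89 to 446 ± 204 (log2 3.15 ± 0.30; limma adjusted p = 0.00402). Entpd6, a Golgi nucleotidase, fell from 48.2 ± 0.831 to 24.7 ± 3.10 (log2 -0.96 ± 0.09; limma adjusted p = 0.00401). On GRCm38, Cd74 (ENSMUSG00000024610) lies on chromosome 18 from 60803848 to 60812652 and Ccl5 (ENSMUSG00000035042) on chromosome 11 from 83525778 to 83530518. C4b (ENSMUSG00000073418) lies on chromosome 17 from 34728380 to 34743882, and Entpd6 (ENSMUSG00000033068) on chromosome 2 from 150749042 to 150771675. These 4 genes changed in the same direction in each of the 3 mice and kept their call without each library in turn.

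Among the 10 largest rises of genes that rose in each mouse, 6 were immunoglobulin segments, which antibody-secreting cells transcribe and whose reads can be shared between near copies. Igkj4 stood at 17.1, 62.5 and 52.2 on the injected sides of mice 1, 2 and 3, Igkj2 at 9.20, 63.6 and 70.0, and Igkj3 at 8.57, 26.0 and 33.2, and all 3 genes were listed at 0 in each uninjected library. Ighg2b rose by 5.34 ± 0.83 log2 units, Ighg2c by 5.25 ± 0.45 and Igkv5-39 by 5.23 ± 0.58 (limma adjusted p = 0.0186, 0.00303 and 0.00657). Cxcl10, an interferon-induced chemokine, rose by 5.35 ± 0.67 log2 units (limma adjusted p = 0.00995). The GTPases Igtp and Iigp1, which act against intracellular pathogens, rose by 5.27 ± 0.34 and 5.20 ± 0.37 (limma adjusted p = 0.00225 each). Without the uninjected library of mouse 1 or of mouse 2, Igkj2, Cxcl10 and Ighg2b no longer passed (highest adjusted p 0.0539, 0.0601 and 0.0729). Ighg2b was also lost without uninjected mouse 3.

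In all, limma called 678 genes higher and 230 lower of 15453 tested, of which 453 and 5 changed by more than 2-fold. With each library centred on its median the calls were 634 higher and 468 lower, so the share of calls that were higher moved from 74.7% to 57.5%. With mouse as a block there were 570 higher and 148 lower, of which 515 and 111 were among the calls made without the block. The 908 calls became 139, 117 and 180 without the uninjected library of mouse 1, 2 and 3, and 1924, 511 and 198 without the injected library of mouse 1, 2 and 3.

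**Figure D1:**
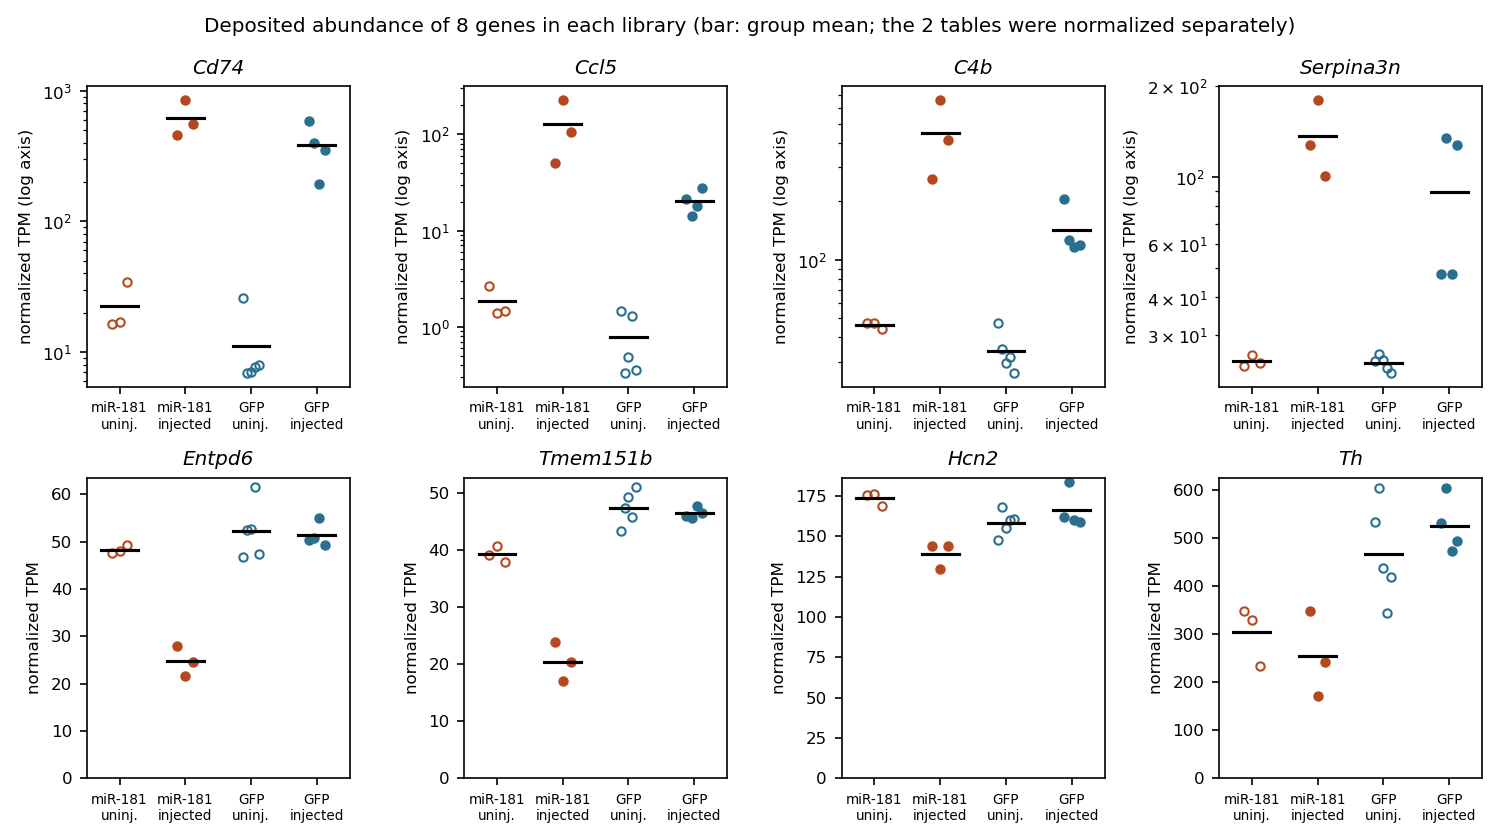
Normalized abundance (y axis; log scale for Cd74, Ccl5, C4b and Serpina3n, linear from 0 for Entpd6, Tmem151b, Hcn2 and Th) of 8 genes in each library of the miR-181 and GFP mice. Open points are uninjected sides, filled points injected sides and bars group means; the 2 sets were normalized separately, and Entpd6 stands between 21.7 and 27.9 on the miR-181 injected sides and between 46.8 and 61.5 in the GFP libraries.

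Several immune gene lists fixed before the data were examined rose, tested against the other genes by camera in limma. All 28 measured interferon response genes rose (28 adjusted over the list alone; median log2 3.29, camera adjusted p = 8.4e-27, adjusted p = 0.292 with an estimated correlation), among them Gbp2, from 4.68 ± 1.12 to 77.4 ± 31.5. All 14 MHC class I genes rose (14 adjusted over the list alone; median 3.58, camera adjusted p = 2.14e-18, adjusted p = 0.29 with an estimated correlation), with the peptide transporter Tap1 going from 4.20 ± 0.325 to 66.6 ± 30.1. Of 7 MHC class II genes 6 rose (7 adjusted over the list alone; median 4.03, camera adjusted p = 9.49e-11, adjusted p = 0.29 with an estimated correlation), led by Cd74 and H2-Aa (log2 4.37 ± 0.30). Of 15 complement genes 10 rose (14 adjusted over the list alone; median 1.49, camera adjusted p = 3.3e-13, adjusted p = 0.3 with an estimated correlation), including C3 at 3.80 ± 0.25 and C1qc at 1.90 ± 0.21 log2 units.

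Lists of microglia, monocytes and macrophages, reactive astrocytes and lymphocytes rose too, while other glial lists did not pass. Of 24 microglia activation genes 22 rose (22 adjusted over the list alone; median 1.77, camera adjusted p = 1.64e-22, adjusted p = 0.225 with an estimated correlation). Cst7, Clec7a and Gpnmb, which phagocytic microglia switch on, rose by 4.87 ± 0.35, 3.72 ± 0.22 and 2.69 ± 0.14 log2 units. Of 12 homeostatic microglia genes 8 rose (10 adjusted over the list alone; median 0.78, camera adjusted p = 2.26e-08, adjusted p = 0.29 with an estimated correlation). Of 14 reactive astrocyte genes 7 rose (7 adjusted over the list alone; median 0.69, camera adjusted p = 9.77e-07, adjusted p = 0.29 with an estimated correlation), led by the protease inhibitor Serpina3n, from 24.6 ± 1.04 to 136 ± 40.3. Gfap, the astrocyte filament, rose by 0.97 ± 0.16 log2 units (limma adjusted p = 0.0206), and the microglial gene Aif1 from 12.9 ± 2.54 to 54.1 ± 16.6 (limma adjusted p = 0.00748). Of 17 T and NK cell genes 10 rose (16 adjusted over the list alone; median 2.36, camera adjusted p = 1.19e-11, adjusted p = 0.343 with an estimated correlation), including Cd3g at 3.49 log2 units. Of 8 B and plasma cell genes 6 rose (7 adjusted over the list alone; median 3.18, camera adjusted p = 8.11e-06, adjusted p = 0.314 with an estimated correlation), including Igkc at 5.19. Of 8 monocyte and perivascular macrophage genes 3 rose (4 adjusted over the list alone; median 0.82, camera adjusted p = 0.0039, adjusted p = 0.47 with an estimated correlation). Aif1 lost its call without uninjected mouse 2 (adjusted p = 0.0539) and Igkc without uninjected mouse 1 or 2 (up to 0.0588). Gfap and Cd3g lost theirs without uninjected mouse 1, 2 or 3 or injected mouse 3 (up to 0.0938 and 0.0957). The astrocyte (median -0.03), oligodendrocyte (-0.03), oligodendrocyte precursor (-0.05) and neutrophil (0.72, 2 genes measured) lists did not pass (camera adjusted p = 0.69, 0.441, 0.37 and 0.227). Without uninjected mouse 3 the oligodendrocyte list passed downward (-0.11, adjusted p = 0.0316).

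Besides Entpd6, the membrane protein Tmem151b was among the largest falls of genes lower in each mouse, from 39.3 ± 1.44 to 20.4 ± 3.46 (log2 -0.94 ± 0.12; limma adjusted p = 0.00995). Others were Epn3, Hapln4, Slitrk1, Hsd17b7, Umad1, Asah2 and Mtx3, with log2 changes between -0.88 and -0.82 and limma adjusted p between 0.0247 and 0.0435. With mouse as a block Hsd17b7 and Mtx3 did not pass (adjusted p = 0.0636 and 0.0553). Tmem151b lost its call without uninjected mouse 1 or 2 (up to 0.0641). The 7 others lost it without any 1 uninjected library or without injected mouse 3 (up to 0.164). Epn3, Hsd17b7 and Mtx3 were also lost without injected mouse 2.

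The 20 voltage-gated ion channel genes, which set the firing of neurons, were lower as a list (median log2 -0.23, camera adjusted p = 4.67e-07, adjusted p = 0.322 with an estimated correlation). Among them Kcnab3 fell by 0.63, Scn8a by 0.47 and Hcn2 by 0.32 log2 units. Their limma adjusted p lay between 0.0224 and 0.0466, and Kcnab3 did not pass with mouse as a block (adjusted p = 0.0566). Of 24 oxidative phosphorylation genes 1, Uqcrfs1, fell by 0.27 (limma adjusted p = 0.0262; 0.0551 with mouse as a block), and 9 adjusted over the list alone (median -0.11, camera adjusted p = 8.62e-07, adjusted p = 0.343 with an estimated correlation). These 4 genes each lost their call without any 1 uninjected library or without injected mouse 3 (up to 0.16). Kcnab3, Scn8a and Uqcrfs1 were also lost without injected mouse 2.

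Single dopamine neuron genes did not pass, while camera called their list lower at the preset correlation, a call that rested on mouse 2. Th, the rate-limiting enzyme of dopamine synthesis, stood at 254 ± 89.1 on the injected and 304 ± 60.8 on the uninjected side (log2 -0.30 ± 0.26; limma adjusted p = 0.55). The dopamine transporter Slc6a3 stood at 301 ± 134 and 380 ± 92.5 (limma adjusted p = 0.527), and the vesicular transporter Slc18a2 at 76.1 ± 39.4 and 111 ± 13.8 (limma adjusted p = 0.321). By mouse, Th differed by 0.00, -0.94 and 0.05 log2 units. Of 23 dopaminergic neuron genes 0 passed over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (limma; median log2 -0.25, camera adjusted p = 0.00542, adjusted p = 0.687 with an estimated correlation). By mouse, the medians of this list were 0.00, -0.76 and 0.05. Its camera call was lost without the uninjected library of mouse 2 (median -0.17, adjusted p = 0.0506) or the injected one (median -0.04, adjusted p = 0.334), and without both the median was 0.01 (adjusted p = 0.918). Of 16 pan-neuronal genes 0 passed over all genes and 0 adjusted over the list alone, with 10 at an unadjusted p under 0.05 (limma; median -0.15, camera adjusted p = 0.000336, adjusted p = 0.436 with an estimated correlation).

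Matches to the miR-181 seed, the bases by which a microRNA pairs with its targets, were counted in the longest annotated 3' UTR of each gene. Entpd6 carried 3 matches in a 3' UTR of 948 bases, Slitrk1 carried 2 and Mtx3 5. Of the genes called lower, 128 of 217 with a 3' UTR (59.0%) had a match, against 23.9% of the 14280 tested (two-sided Fisher's exact test p = 8.61e-29, across genes, which are not independent replicates). Of the genes called higher, 124 of 639 (19.4%) had one. Median log2 changes were 0.02 in genes without a match and -0.04, -0.09, -0.11 and -0.12 in genes with 1, 2, 3 and 4 or more. On the GFP side the same medians were 0.01, -0.01, -0.05, -0.06 and -0.08. Genes with a match differed from genes without one by -0.0748 log2 units with miR-181 and -0.0387 with GFP; compared within 18 bins of 3' UTR length, by -0.0603 and -0.0145. Ranked among 16217 heptamers counted in the same 3' UTRs, from the most negative rank-sum score, the miR-181 heptamer TGAATGT stood at 1 on the miR-181 side and at 991 of 16214 on the GFP side. There the 8-base matches alone and the fits without injected mouse 4 or uninjected mouse 1 put it within the lowest 5 percent. Of 25 reported miR-181 targets, Carm1 and Cbx7 fell by 0.46 and 0.42 log2 units while Tgfbr1 and Mcl1 rose by 0.75 and 0.34 (limma adjusted p between 0.0126 and 0.0415; Mcl1 0.0596 with mouse as a block). Adjusted over the list alone 3 rose and 5 fell (median log2 -0.01, camera adjusted p = 0.453). These 4 lost their calls without uninjected mouse 1 or 2 (up to 0.164), and all but Tgfbr1 also without uninjected or injected mouse 3. The host transcript Mir181a-1hg did not reach the mean of 1 needed for testing, and mature miR-181 was not measured.

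**Figure D2:**
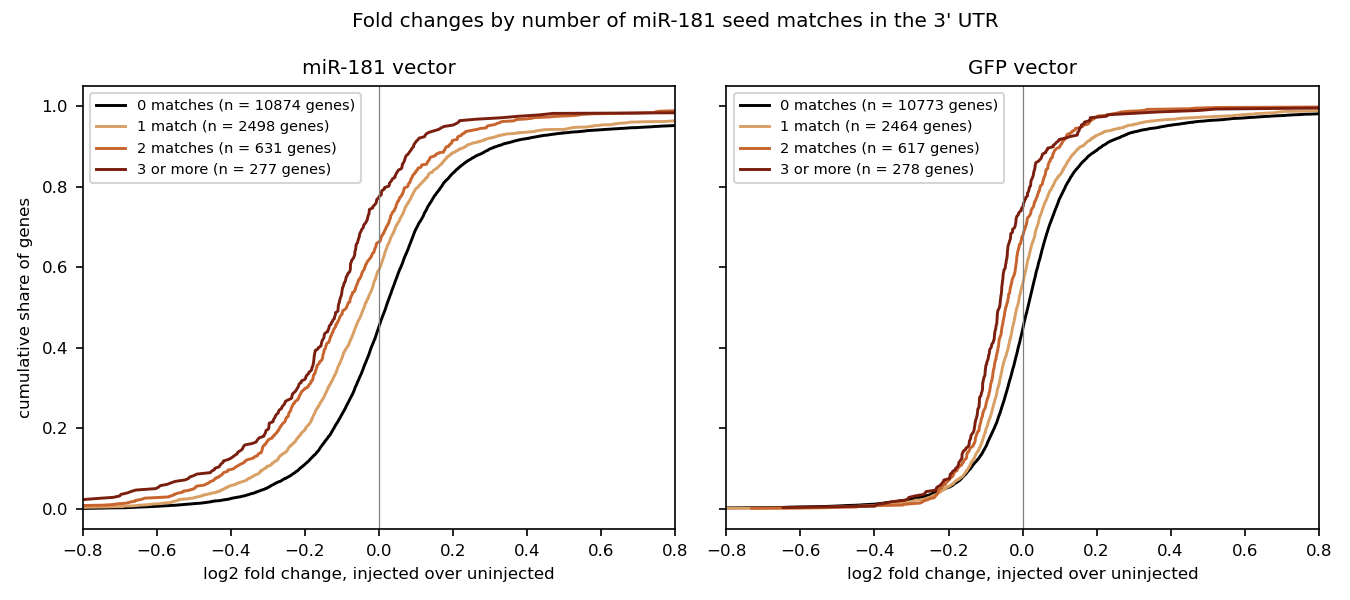
Cumulative share of genes (y axis) by log2 change, injected over uninjected (x axis), for genes with 0, 1, 2 and 3 or more miR-181 seed matches in the 3' UTR, on the miR-181 side and the GFP side. Curves with more matches lie further left on both sides; genes with 2 matches have a median of -0.09 on the miR-181 side and -0.05 on the GFP side, against 0.02 and 0.01 without a match.

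The second comparison asked what the injection and a virus without miR-181 changed. H2-Eb1, a chain of MHC class II, rose from 4.17 ± 1.88 (SD, n = 5) to 97.9 ± 38.7 (n = 4), a log2 change of 4.39 ± 0.31 (SE; limma adjusted p = 0.000344). Cd74 rose from 11.1 ± 8.33 to 382 ± 160 (log2 5.14 ± 0.41; limma adjusted p = 0.000401), and H2-Aa from 3.51 ± 3.82 to 119 ± 48.8 (log2 5.15 ± 0.51; limma adjusted p = 0.00104). Ctss, a lysosomal protease of microglia, rose from 100.2 ± 17.0 to 286 ± 38.7 (log2 1.51 ± 0.12; limma adjusted p = 0.000401). H2-Eb1 (ENSMUSG00000060586) lies on chromosome 17 from 34305867 to 34316674 and Ctss (ENSMUSG00000038642) on chromosome 3 from 95526786 to 95556403 of GRCm38. These 4 genes rose in each of 4 mice and kept their call without each library in turn. Among the other large rises were H2-Ab1 at 4.57, Ccl5 at 4.08 ± 0.31, Cxcl9 at 3.64 (0.0527 with mouse as a block) and Cxcl10 at 3.31 ± 0.50 log2 units. The immunoglobulin genes Igkc, Igkv5-39 and Ighv1-26, whose reads can be shared between copies, rose by 5.18 ± 0.93, 4.52 and 4.25. Igkc did not pass with mouse as a block (adjusted p = 0.173). These 3 genes each passed in 4 or fewer of the 9 fits that left out 1 library (up to 0.153). Each was lost without injected mouse 2 or 4 or uninjected mouse 2 or 5.

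In all, limma called 204 genes higher and 2 lower of 15274 tested on the GFP side, with 123 and 1 beyond 2-fold and 1454 genes at an unadjusted p under 0.05. Both libraries of mouse 1 also carried the pituitary hormones Prl and Gh (4.71% of the uninjected and 0.227% of the injected library). The 2 lower genes, chosen after their values were seen, were Gm49376, a predicted gene that fell from 4.31 ± 1.04 to 1.34 ± 0.575 (limma adjusted p = 0.021), and 4933434E20Rik, which fell from 91.1 ± 2.62 to 78.8 ± 2.05 (limma adjusted p = 0.0223). With mouse as a block neither passed (0.203 and 0.109), and 2 other genes were called lower. Gm49376 and 4933434E20Rik passed in 2 and 3 of the 9 fits that left out 1 library (limma adjusted p up to 0.0748 and 0.0817). The block left 122 higher genes, of which 108 were among the 204. The total of 206 became 126, 130 and 115 without injected mouse 1, 2 and 4, with 3, 4 and 3 genes lower, and 133, 114 and 108 without uninjected mouse 2, 3 and 5, where 1, 0 and 0 genes were lower. It was 211 without injected mouse 3, with 8 lower, and 255 without uninjected mouse 1, with 4 lower.

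The immune lists rose in the GFP mice as well. Of 28 interferon response genes 18 rose (26 adjusted over the list alone; median log2 1.49, camera adjusted p = 7.34e-35, adjusted p = 0.181 with an estimated correlation). Of 14 MHC class I genes 12 rose (14 adjusted over the list alone; median 2.17, camera adjusted p = 1.16e-31, adjusted p = 0.125 with an estimated correlation). H2-D1 went from 66.9 ± 10.5 to 378 ± 137 and B2m from 188 ± 25.8 to 785 ± 261. Of 7 MHC class II genes 5 rose (7 adjusted over the list alone; median 4.39, camera adjusted p = 3.32e-18, adjusted p = 0.125 with an estimated correlation). Of 23 microglia activation genes 16 rose (20 adjusted over the list alone; median 1.07, camera adjusted p = 2.52e-34, adjusted p = 0.125 with an estimated correlation), among them Aif1 at 1.13 ± 0.11. Of 14 complement genes 9 rose (12 adjusted over the list alone; median 1.12, camera adjusted p = 1.83e-23, adjusted p = 0.132 with an estimated correlation), with C1qa at 1.37 ± 0.12 and C4b at 2.04 ± 0.20. Of 14 reactive astrocyte genes 3 rose (8 adjusted over the list alone; median 0.55, camera adjusted p = 6.45e-08, adjusted p = 0.197 with an estimated correlation). Among them were Gfap at 0.83 ± 0.17 (limma adjusted p = 0.0492) and Serpina3n at 1.69 ± 0.31 (limma adjusted p = 0.0249; 0.0841 with mouse as a block). Gfap and Serpina3n passed in 2 and 3 of the 9 fits that left out 1 library, both lost without injected mouse 2 or 4 or uninjected mouse 2, 3, 4 or 5 (up to 0.153 and 0.0743), and Gfap without injected mouse 1.

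Neuronal genes showed few changes on the GFP side. Th stood at 525 ± 57.3 on the injected and 468 ± 102 on the uninjected side (log2 0.19 ± 0.15; limma adjusted p = 0.743). Slc6a3 stood at 549 ± 53 and 521 ± 99, and Slc18a2 at 130 ± 8.16 and 128 ± 22.1 (limma adjusted p = 0.869 and 0.961). Of 23 dopaminergic neuron genes 0 passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 (limma; median log2 0.13, camera adjusted p = 0.0837, and 0.00185 with mouse as a block). Without injected mouse 3, or uninjected mouse 1, 2 or 5, that list passed upward (adjusted p = 0.0202, 0.0258, 0.000176 and 0.0332). Of 20 ion channel genes 0 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 (limma; median -0.09, camera adjusted p = 0.00132, adjusted p = 0.432 with an estimated correlation). Of 24 oxidative phosphorylation genes 0 passed either way, with 1 at an unadjusted p under 0.05 (limma; median 0.02, camera adjusted p = 0.357). Of 16 pan-neuronal genes 0 passed either way, with 1 at an unadjusted p under 0.05 (limma; median 0.00, mean -0.00, camera pointing down, adjusted p = 0.592). After quantile normalization that median was -0.05 and the list passed (adjusted p = 0.0288).

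**Figure D3:**
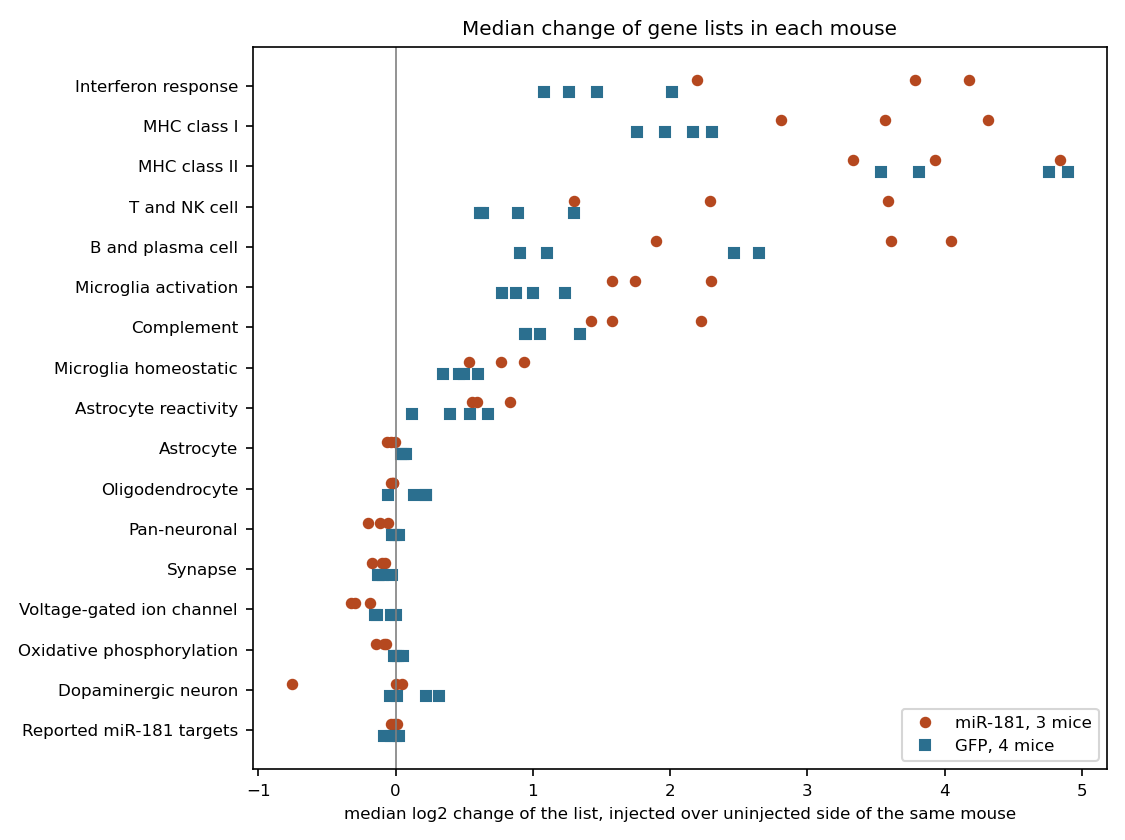
Median log2 change, injected over uninjected (x axis), of the measured genes of 17 lists (y axis) in each mouse; circles are the 3 miR-181 mice and squares the 4 GFP mice. Interferon, MHC and microglia lists lie above 0 in each mouse of both sets, and the dopaminergic neuron list lies at -0.76 in miR-181 mouse 2 and between -0.04 and 0.31 in the other mice.

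The third comparison asked whether the change with miR-181 differed from the change with GFP, from the log2 change within each of 3 and 4 mice. Entpd6 differed by -0.95 ± 0.10 (SE; mean change -0.96 with miR-181 and -0.01 with GFP; limma adjusted p = 0.0455). Chchd10, a mitochondrial protein, differed by -0.87 ± 0.10 and Lamp5 by -0.82 ± 0.09 (limma adjusted p = 0.0455 each). In the first comparison Lamp5 passed only with mouse as a block (adjusted p = 0.424, and 0.0102 with the block). These genes carried 3, 0 and 0 seed matches. The other 2 calls were gene models: Gm8430, a processed pseudogene on chromosome 6 from 122456904 to 122457374, differed by 4.32 ± 0.30 (limma adjusted p = 0.00518), and Gm21830 passed at 0.0455. Gm8430 lay at 0.00964 or less on the uninjected sides of the miR-181 mice and between 75.3 and 188 in the GFP libraries, which were normalized separately. Gm21830 was listed at 0 on each miR-181 injected side and stood at 2.82, 4.77 and 7.78 on the uninjected sides of mice 1, 2 and 3. In the GFP set it stood at 5.56 and 4.72 on the injected and uninjected sides of mouse 1 and was listed at 0 in the other 7 libraries. Reads of both models can be shared with near copies.

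Over all 14824 genes, limma called 1 higher and 4 lower, with 2268 at an unadjusted p under 0.05. Without miR-181 mouse 1 there were 169 higher and 154 lower; without any other mouse there were 1 or 2 calls, and Gm8430 alone passed without each mouse in turn. Iigp1 and Irf1, an interferon-induced transcription factor, differed by 3.19 and 1.73 log2 units without passing (limma adjusted p = 0.0691 and 0.0726), likewise Psmb9 by 1.73 (0.0866). Without miR-181 mouse 1 all 3 passed (0.0121 each). Th differed by -0.47 (limma adjusted p = 0.392), and by between -0.64 and -0.14 with 1 mouse left out, the latter without miR-181 mouse 2.

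By list, the interferon response genes rose further with miR-181, with a median difference of 1.76 log2 units (of 28, 0 over all genes and 26 adjusted over the list alone, 26 at an unadjusted limma p under 0.05; camera adjusted p = 1.1e-21, adjusted p = 0.292 with an estimated correlation). MHC class I differed by 1.47 (of 14, 0 over all genes and 14 adjusted over the list alone, 14 unadjusted; camera adjusted p = 1.46e-12, adjusted p = 0.292 with an estimated correlation). MHC class II did not pass, with a median of -0.25, a mean of 0.03 and camera pointing up (of 7, 0 either way and 2 unadjusted; adjusted p = 0.549). Microglia activation differed by 0.58 (of 23, 0 over all genes and, adjusted over the list alone, 15 higher and 1 lower, 17 unadjusted; camera adjusted p = 2.77e-09, adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation differed by -0.14 (of 24, 0 over all genes and 10 lower adjusted over the list alone, 13 unadjusted; camera adjusted p = 2.07e-06, adjusted p = 0.363 with an estimated correlation). Ion channels differed by -0.16 (of 20, 0 over all genes and 5 lower adjusted over the list alone, 10 unadjusted; camera adjusted p = 1.72e-05, adjusted p = 0.347 with an estimated correlation). The dopaminergic neuron list differed by -0.39 (of 23, 0 over all genes and 0 adjusted over the list alone, 3 unadjusted; camera adjusted p = 2.43e-05, adjusted p = 0.515 with an estimated correlation), but by -0.11 without miR-181 mouse 2 (camera adjusted p = 0.022). Genes with a seed match differed from genes without one by -0.05 in median (-0.0486 within length bins), and TGAATGT stood at rank 1 of 16211 heptamers. The seed shift of single mice, -0.08 ± 0.04 with miR-181 and -0.04 ± 0.02 with GFP (SD, n = 3 and 4), did not differ by an exact two-sided permutation test (p = 0.2; smallest possible 0.0286).

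Both vectors raised many of the same genes. Of the 14824 genes tested in both, 606 were called higher with miR-181 and 202 with GFP. Of these, 187 were called higher in both, against 8.26 for independent lists. Of these 187, 182 had the larger change with miR-181 (median log2 2.07 against 1.21), and 15 genes were called higher with GFP alone. Of 229 genes lower with miR-181 and 2 with GFP, 0 were shared (0.0309 for independent lists). Across genes, which are not independent replicates, the 2 sets of changes had a Spearman correlation of 0.31. Between single mice of the 2 sets it ran from 0.0788 to 0.273 over 12 pairs. The shared count of 187 became 78, 74 and 97 without uninjected miR-181 mouse 1, 2 and 3 and 102 without injected miR-181 mouse 3. Without injected GFP mouse 1, 2 and 4 it was 113, 120 and 98, and without uninjected GFP mouse 2, 3 and 5 it was 124, 109 and 102.

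**Figure D4:**
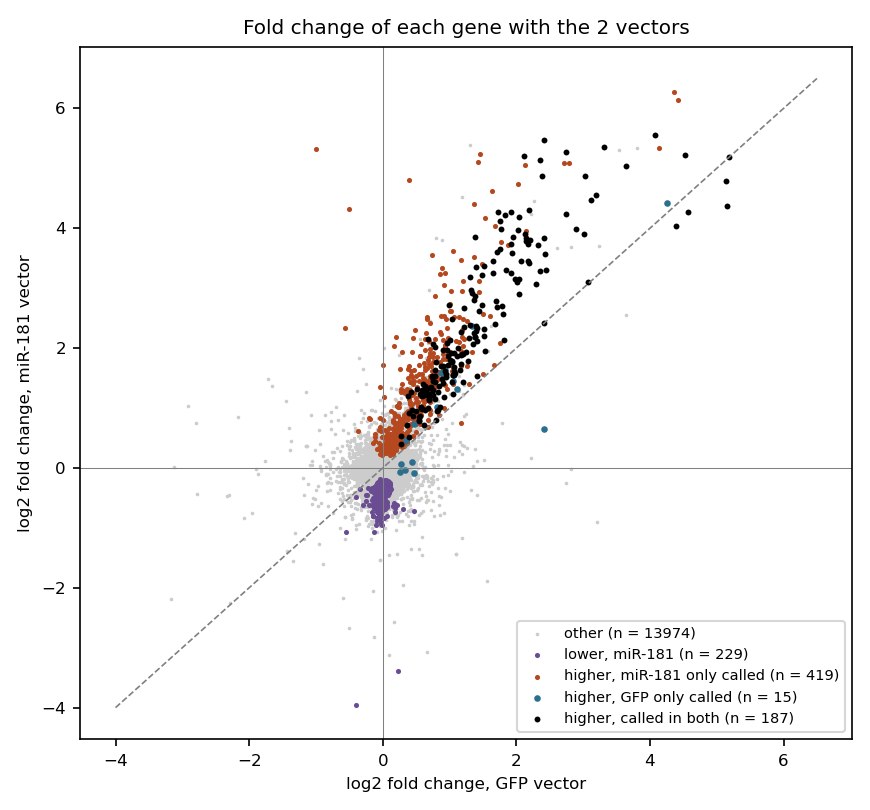
Log2 change with miR-181 (y axis) against log2 change with GFP (x axis) for the 14824 genes tested in both, each from injected over uninjected. The dashed line marks equal changes. Points show 187 genes called higher in both, 419 called higher with miR-181 only, 15 called higher with GFP only, 229 called lower with miR-181 and 13974 others. A gene called with 1 vector only need not differ between the vectors: limma called 1 gene higher and 4 lower for the difference.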

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

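The tests of read spillover and of the seed shift and heptamer rank in single mice were chosen only after the results they concern were seen. The test of pituitary tissue was written after the 5 hormones were seen, but before its other 12 genes were looked at. The other tests here were fixed before.

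In the GFP set, the gap from the highest or lowest library to its nearest neighbour was divided by the range of its group of 4 or 5 libraries. Of 144 groups, 18 passed Dixon's 95% critical value, against 7.2 by chance, which picks out about 1 in 20 groups if values are normally distributed. The values were not logged and several genes stood out in the same library, so 7.2 is only a rough guide. These counts leave out Gm21830 and the 5 pituitary hormones, which were looked at because their values stood out and passed in all 12 of their groups. The uninjected library of mouse 1 stood highest in 7 of the 18 and for Gm21830. It held Cd74 at 26.0 against at most 8.02 in the other uninjected libraries (gap over range 0.941), H2-Aa (0.869), H2-Ab1 (0.751), Lyz2 (0.771), B2m (0.727), Ighg2b (0.835), and Igkj3 and Gm21830, which were listed at 0 in the other 4 (1 each). The injected library of mouse 1 stood highest for C4b, at 204.7 against at most 127 (0.881), for Cxcl10 (0.838) and for Gm21830 (1). Injected mouse 2 stood highest for Igkj4, at 747 against at most 58.0 (0.922), Ighg2b (0.961) and Hcn2 (0.871), and lowest for Tgfbr1 (0.921). Uninjected mouse 3 stood highest for Igkv5-39 (0.757) and Cxcl9 (0.862), uninjected mouse 4 for Hsd17b7 (0.800) and Ighv1-26 (0.847), and uninjected mouse 5 for Lamp5 (0.783).

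Both GFP libraries of mouse 1 also stood apart for pituitary hormones. Prl, made by the anterior pituitary, was at 30138 on the uninjected and 1661 on the injected side, against at most 9.28 in the other 7 libraries (gap over range 0.9997 and 0.998). Gh stood at 18734 and 642 against at most 3.47 (0.9998 and 0.998). Pomc stood at 607 and 118 (0.996 and 0.995), Cga at 499 and 20.8 (0.999 and 0.9905) and Lhb at 69.2 and 3.04 (0.998 and 1). Prl and Gh made up 4.71% of the uninjected and 0.227% of the injected library.

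Pituitary tissue in the dissected samples may have been the source of these transcripts. Of 12 pituitary genes not looked at before, 9 had their highest value of the 9 GFP libraries in the uninjected library of mouse 1, and the same 9 their second highest in the injected one; 4 of the 12 reached 1 in the other libraries too. Spillover of reads between the 2 libraries would keep 1 ratio, but the injected-to-uninjected ratio of the 5 hormones ran from 0.0343 for Gh to 0.195 for Pomc, a factor of 5.69. Among the 5 this spread rests on Pomc, since Cga, Lhb and Prl lay at 0.0416, 0.0439 and 0.0551, near Gh. Whether another sample was mixed in after dissection was not tested. No biological explanation was tested, since the design names none.

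Genes with a 3' UTR match to the miR-181 seed shifted by -0.0452 log2 units more with miR-181 than with GFP, and may be lower through pairing with miR-181. Length and base composition of the 3' UTR, which act on other heptamers too, are argued against by the rank of TGAATGT, 1 of 16217. A lower share of neurons on the injected side stays open: neuronal genes with a match differed from those without by -0.0642 (29 of 98 genes, one-sided permutation p = 0.114), the outcome written beforehand for this explanation, but the genes are few. With GFP, where no miR-181 was given, the same genes differed by -0.0769 (one-sided permutation p = 0.00328). Injection and virus as such stay open too: the shifts of single mice overlapped, as written for that explanation (exact two-sided p = 0.2; smallest possible 0.0286), and the test of ranks, added after that, placed each miR-181 mouse (2, 1 and 1) below each GFP mouse (4425, 1076, 149 and 1009) at an exact two-sided p = 0.0571. With 3 and 4 mice, and with dose and library set differing as well, these cannot be told apart from an effect of miR-181.

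The change differed between the vectors by limma for Gm8430 (log2 4.32, higher with miR-181), Gm21830 (-3.45 on the log2(value + 0.5) scale, with injected miR-181 libraries listed at 0), Entpd6 (-0.95), Chchd10 (-0.87) and Lamp5 (-0.82), and by camera for 20 lists. With medians in log2 units, the lists with a higher change under miR-181 than under GFP were interferon response (1.76), MHC class I (1.47), B and plasma cell (1.38), T and NK cell (1.20), complement (0.73) and proliferation (0.60). Next were cytokine and NF-kB (0.59), microglia activation (0.58), immediate early (0.32), homeostatic microglia (0.30), p53 response (0.20) and ER stress (0.11). Those with a lower change under miR-181 than under GFP were serotonergic (-0.46) and dopaminergic neuron (-0.39), oligodendrocyte (-0.17), ion channel (-0.16), oligodendrocyte precursor (-0.15), GABAergic neuron (-0.14), oxidative phosphorylation (-0.14) and pan-neuronal (-0.14). The oligodendrocyte difference comes mostly from a rise with GFP (median 0.12, camera adjusted p = 0.000542, adjusted p = 0.436 with an estimated correlation, and 0.0519 without both libraries of GFP mouse 1). With miR-181 that list did not pass (median -0.03, adjusted p = 0.441). None of the 20 calls held with an estimated correlation (adjusted p between 0.181 and 0.515). With a filter 5 times as high T and NK cell, cytokine and NF-kB, and B and plasma cell did not pass (medians 1.13, 0.14 and 1.36, camera adjusted p = 0.0781, 0.0862 and 0.197). With a smaller pseudocount B and plasma cell did not pass (0.055), nor did serotonergic with median centring (0.0554). The dopaminergic difference rests largely on miR-181 mouse 2: without it the median was -0.11 (camera adjusted p = 0.022). Without that mouse T and NK cell fell to 0.65, cytokine and NF-kB to 0.32 and homeostatic microglia to 0.17 (camera adjusted p = 0.0337, 0.00118 and 0.0251), and without GFP mouse 1 B and plasma cell fell to 0.80. The serotonergic difference rests on 2 of 5 listed genes, since the other 3, among them Tph2 and Slc6a4, were too low in the GFP table. Whether the same region was dissected in both sets was not tested. T and NK cell had 17 genes measured with miR-181 but 6 with GFP, and B and plasma cell 8 and 6. The differences of these 2 lists therefore rest on at most 6 genes each. Of the 20, the calls of 3 lists were lost in at least 1 fit that left out a mouse. B and plasma cell was lost without miR-181 mouse 2 or 3 or GFP mouse 1 or 3 (adjusted p = 0.097, 0.0634, 0.136 and 0.118). Serotonergic was lost without miR-181 mouse 2 or GFP mouse 2 or 3 (0.108, 0.0707 and 0.0572), and oligodendrocyte precursor without miR-181 mouse 1 (0.152).

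Other splits of the libraries were refitted with limma to ask whether any grouping gives as many calls. For miR-181 the 10 splits are too few for a share under 0.05; the real split called 908 genes and the highest other 2, also among the 3 others that part all 3 pairs. For GFP, 1 of 100 splits, the real one, called as many as 206 genes, and the highest other called 2, which argues against chance where pairs are ignored. Only 14 of these splits, the real one among them, part all 4 pairs, too few for a share under 0.05; the highest of the 13 others called 2. For the difference, 1 of 35 splits, the real one, called as many as 5 genes and the highest other 2. That is the smallest share 35 splits allow, so it argues against chance for that count but cannot exclude it. With a pseudocount 5 times as high, 0 genes were called higher and 0 lower.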

How the results depend on the processing

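Keeping repeated rows, rescaling each library to the same sum, and leaving out both libraries of miR-181 mouse 2 or of GFP mouse 1 were chosen only after the data were seen; the other alternatives were planned. The cause was not tested unless a sentence gives it.

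Fewer or more genes tested changed the counts. With no filter but a mean above 0, the miR-181 comparison called 315 genes (268 higher, 47 lower), 7 genes were lower with GFP, 1 differed between the vectors (0 lower), 106 were higher in both and the Spearman correlation across genes was 0.222. With a filter 5 times as high, GFP gave 136 calls (135 higher, 1 lower), 124 genes were higher in both, and the glutamatergic list median of the difference reversed to 0.85. With a pseudocount 5 times as high, 0 genes differed between the vectors by limma (0 higher, 0 lower), against 2268 at an unadjusted p under 0.05 in the reported fit.

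Without the intensity trend, limma called 449 genes with miR-181 (395 higher, 54 lower) and 3 for the difference (2 higher, 1 lower). Median centring gave 468 lower genes with miR-181 and 4 lower with GFP. Quantile normalization gave 4 lower with GFP, 1 for the difference (0 lower), and a reversed GFP median of the pan-neuronal list, -0.0526 (adjusted p = 0.0288). With all repeated rows kept there were 912, 212 and 5 calls in the 3 comparisons.

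With mouse as a block, which uses the pairing, 148 genes were lower with miR-181, GFP gave 124 calls (122 higher), and 114 genes were higher in both. Among lists the block brought in the serotonergic list with miR-181 (adjusted p = 0.0458) and the dopaminergic list with GFP (adjusted p = 0.00185). Beside the gene calls given in the report and those of Trp53inp1, Zfp971, C3, Gpnmb and Clec7a given with the other observations, it changed no other call of a gene named in the text.

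Leaving out both libraries of miR-181 mouse 2 gave 107 calls (103 higher, 4 lower), 76 genes higher in both, and a dopaminergic median that reversed to 0.0113. Leaving out both libraries of GFP mouse 1 left 1 gene lower. Fewer libraries lower the power of these fits.

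The Wald q-values of the authors, over all genes of their tables, called 1915 genes with miR-181 (1176 higher, 739 lower) and 318 with GFP (316 higher). Their likelihood ratio q-values called 979 and 186, with 0 lower for GFP against 2 by limma and 1454 genes at an unadjusted limma p under 0.05. Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons where the preset correlation called 24, 18 and 20, and fry called 15 with miR-181 and 9 for the difference. On the GFP side the seed heptamer passed into the lowest 5 percent for 8-base matches (shift -0.0425) and in coding sequences (shift -0.0289).

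Leaving out 1 library at a time, the miR-181 total ran from 117 to 1924 (113 to 1210 higher, 4 to 714 lower) and the GFP total from 108 to 255 (108 to 251 higher, 0 to 8 lower). Leaving out 1 mouse at a time, the difference total ran from 1 to 323 (1 to 169 higher, 0 to 154 lower), with the highest values without miR-181 mouse 1. Genes higher in both ran from 74 to 209 and their Spearman correlation from 0.266 to 0.336. The seed shift ran from -0.0988 to -0.0567 with miR-181, from -0.0485 to -0.0239 with GFP and from -0.0715 to -0.0332 for the difference. Lists called ran from 20 to 24, 18 to 20 and 18 to 21. Of genes named in the text, 32 of 64 called with miR-181, 20 of 33 with GFP and 1 of 5 for the difference passed in each such fit.

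Over all alternatives, lists called in the reported fit kept their call and direction in 1009 of 1146 list-by-setting fits, lost it in 136 and reversed in 1. Lists not called stayed so in 947 of 974, were called in 25 and called after a reversal in 2. Named genes kept a call in 1361 of 1715 fits and lost it in 354, and those not called stayed so in 1884 of 1918 and gained a call in 34. The edgeR quasi-likelihood test, planned for files with counts, was not run, since the files hold none. DESeq2, which also needs counts, was not run either. The limma fits do not separate technical error from the spread between mice. A technical variance per gene is deposited, read so from its column name; its median ratio to the variance within sides was 0.402 with miR-181 and 0.621 with GFP. A gene under a mean of 1 was not tested.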

Other observations

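The follow-up within zinc-finger genes and the choice of genes in this part were made only after the results were seen; the lists and the coding-sequence counts were fixed before.

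Transcripts of the proliferation list rose with miR-181; which cells carried them was not tested. Of 9 proliferation genes 2 rose (7 adjusted over the list alone; median log2 0.78, camera adjusted p = 4.11e-05, adjusted p = 0.375 with an estimated correlation). They were the mitotic kinase Cdk1, from 0.712 ± 0.175 to 3.54 ± 0.924, and the topoisomerase Top2a, from 1.56 ± 0.287 to 4.99 ± 2.13 (SD, n = 3; limma adjusted p = 0.0139 and 0.0445). With GFP, Cdk1 stood at 1.24 ± 0.792 on the uninjected and 1.20 ± 0.627 on the injected side (limma adjusted p = 0.999). With GFP, 0 of 8 proliferation genes passed over all genes or adjusted over the list alone, with 0 at an unadjusted limma p under 0.05. Cdk1 and Top2a lost their calls without any 1 uninjected miR-181 library or without injected mouse 3, and Top2a without injected mouse 2 (highest adjusted p 0.0698 and 0.144).

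Stress lists shifted little. Of 11 ER stress genes with miR-181, 0 passed over all genes and 3 adjusted over the list alone, with 3 at an unadjusted limma p under 0.05 (median 0.18, camera adjusted p = 0.0159, adjusted p = 0.515 with an estimated correlation). Atf4, a transcription factor of the stress response, stood at a log2 change of 0.42 and Chac1, which it induces, at 0.92 (limma adjusted p = 0.0515 and 0.0602). Of 10 p53 response genes 1, Trp53inp1, rose by 0.62 (limma adjusted p = 0.0288; 0.0604 with mouse as a block), and 6 adjusted over the list alone (median 0.27, camera adjusted p = 0.00205, adjusted p = 0.343 with an estimated correlation). The ER stress list did not pass without uninjected mouse 1 or injected mouse 3 (adjusted p = 0.0717 and 0.0598). Of 12 neuronal injury genes 1, the secreted peptide precursor Vgf, fell by 0.42 (limma adjusted p = 0.0102), with 1 higher and 2 lower adjusted over the list alone (median 0.02, mean 0.04, camera pointing down, adjusted p = 0.592). Vgf was lost without uninjected mouse 1 or 2 (up to 0.0666). Trp53inp1 was lost without any 1 library other than injected mouse 1 (up to 0.123).

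In the GFP set, of 6 T and NK cell genes 2 rose (4 adjusted over the list alone; median 0.83, camera adjusted p = 6.58e-07, adjusted p = 0.113 with an estimated correlation). Of 6 B and plasma cell genes 3 rose (3 adjusted over the list alone; median 1.68, camera adjusted p = 7.4e-05, adjusted p = 0.29 with an estimated correlation). Of 7 monocyte and perivascular macrophage genes 1 rose (3 adjusted over the list alone; median 0.45, camera adjusted p = 4.11e-05, adjusted p = 0.197 with an estimated correlation). Of 12 homeostatic microglia genes 5 rose (8 adjusted over the list alone; median 0.49, camera adjusted p = 2.67e-10, adjusted p = 0.225 with an estimated correlation). Csf3r, a receptor of neutrophils and microglia, rose by 1.59 ± 0.16 log2 units with miR-181 and 1.08 ± 0.13 with GFP (limma adjusted p = 0.00505 and 0.00317). Lyz2, a lysozyme of myeloid cells, rose by 2.43 ± 0.14 and 2.42 ± 0.28 (limma adjusted p = 0.00225 and 0.00244). In GFP mice C3, Gpnmb and Clec7a rose by 2.20, 1.72 and 2.32 (limma adjusted p = 0.0058, 0.0249 and 0.0261), and with mouse as a block did not pass (0.074, 0.137 and 0.128). Gpnmb and Clec7a lost their calls in 6 and 7 of the 9 fits that left out 1 library, among them those without injected mouse 2 or 4 or uninjected mouse 2, 3, 4 or 5 (up to 0.0817 and 0.091).

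Synapse genes were lower as a list with both vectors, while mitochondrial genome genes had no steady direction across mice. The 22 synapse genes were lower as a list with miR-181 (median -0.13, camera adjusted p = 0.00348, adjusted p = 0.373 with an estimated correlation). With GFP 0 of them passed over all genes or adjusted over the list alone, with 6 at an unadjusted limma p under 0.05 (median -0.10, camera adjusted p = 4.42e-05, adjusted p = 0.343 with an estimated correlation). Of 13 mitochondrial genome genes 0 passed over all genes or adjusted over the list alone with either vector, with 0 at an unadjusted limma p under 0.05. Their medians were -0.14 with miR-181 (camera adjusted p = 0.0384, adjusted p = 0.688 with an estimated correlation) and -0.27 with GFP (camera adjusted p = 8.11e-06, adjusted p = 0.432 with an estimated correlation). By mouse the mitochondrial medians were 0.10, -0.25 and -0.31 with miR-181 and 0.01, -0.63, -0.05 and -0.11 with GFP, so in mouse 1 of each set they were not lower. After quantile normalization the mitochondrial list passed in neither (adjusted p = 0.615 and 0.545). With miR-181 it was also lost without uninjected mouse 3, injected mouse 2 or injected mouse 3 (0.187, 0.261 and 0.273), with no filter but a mean above 0 (0.0964) and with median centring (0.0986).

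Serotonin neuron genes differed in level between the 2 tables. These were normalized separately, but library sums ran only from 970505 to 1040288, so size factors are too alike to account for the gap. Whether the same region was dissected in both sets was not tested, so tissue content may differ along with the vector. Tph2, which makes serotonin, lay between 22.1 and 54.9 in the miR-181 libraries and between 0.295 and 1.06 in the GFP libraries, and the serotonin transporter Slc6a4 between 14.0 and 35 and between 0 and 0.216. Both genes were looked up after the data were seen.

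Genes with 4 or more miR-181 matches in the coding sequence had a median log2 change of -0.19 with miR-181 (161 genes) and -0.08 with GFP (162 genes), and 10 of the 161 were called lower and 0 higher by limma. Among the 10 were the zinc-finger genes Zfp37 (-0.61, 13 matches), Zfp967 (-0.61, 12 matches) and Zfp971 (-0.74, 13 matches; adjusted p = 0.0335, and 0.0584 with mouse as a block). Zfp37 and Zfp967 lost their calls without uninjected mouse 2 or 3 (up to 0.0598 and 0.0624). Zfp971 lost it without any 1 library other than injected mouse 1 (up to 0.135).

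A candidate explanation is pairing of miR-181 with these coding matches: in coding sequences TGAATGT stood at rank 1 of 16383 heptamers on the miR-181 side, as this explanation needs, and at 811 on the GFP side, but by mouse at 1547, 1 and 1 with miR-181 and 623, 802, 7668 and 829 with GFP (exact two-sided permutation p = 0.629), so single mice overlapped. A fall of zinc-finger genes as a class would leave no relation with matches, but across 360 tested Zfp genes the Spearman correlation of matches with log2 change was -0.476 (one-sided permutation p = 1e-05, the smallest possible). That outcome had been written against a class effect, but the bound was not enough, since the correlation was -0.308 with GFP too, where no miR-181 was given, so a fall that follows match-rich zinc-finger genes for another reason stays open. Injection and virus as such stay open as well: single mice overlapped, the outcome written for that explanation (exact two-sided permutation p = 0.143; smallest possible 0.0286; 3 against 4 mice).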
